A study of Homo sapiens with 12 samples.

How the data were processed

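RNA was extracted with TRIzol from human bronchial epithelial cells of 4 groups, 3 libraries each, and libraries were made with the TruSeq RNA v2 kit, per the labels' protocols. Per the submitters' processing notes, STAR 2.6, featureCounts 1.6.3 from Subread and DESeq2 1.22.1 were used with the hg19 build; the gene annotation, filters and counting options are not given in the sources used here. This kit does not mark strand, so reads from overlapping and antisense genes cannot be told apart: 81 of the 198 genes named by the rule overlap another annotated gene, 59 of them on the opposite strand. Near-identical copies (PRB1 and PRB2, SFTPA1 and SFTPA2, the KRT6 and SPRR families) are uncertain in the same way. The build of the files and of the reference used here (GENCODE v29, another assembly) differ, so no coordinates are given and the reference served only for gene names, overlaps and 3 prime UTRs. Of 26364 symbols in the files, 23775 matched it and 17918 had a 3 prime UTR.

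The authors deposited 3 tables, 1 for each siRNA group against the same controls, with 26364 genes each. Per the file headers and values, each holds for 6 libraries a normalized signal, namely read counts divided by a size factor set within that table, and the authors' DESeq2 result for the comparison: a log2 fold change with its standard error, a deposited test statistic (a score) and a deposited p-value with its adjusted form. The planned test for raw counts did not apply, because the files held normalized values, and the test planned for such values was used. Dividing each column by the value of 1 read, estimated from its low values, gave whole reads recovered for 100% of the values above 0 within 0.01, and the reads recovered for the controls differed between tables for 0 genes. The recovered totals were 22622358 to 33529530 reads per library, and the 10 most abundant genes took 9.07% to 10.1% of them. These totals set the counting precision. Genes with few reads, such as MUC5AC and FOXA3, could not be tested. The chi-square per degree of freedom between libraries of a group was 6.68 to 25.6, so no library looked like a second copy of another. It was highest between double knockdown replicates 1 and 3 (25.6) and FOXA1 knockdown replicates 1 and 3 (22.6). Double knockdown replicate 1, the library with the fewest reads, was at 17.0 from replicate 2, against 6.68 between replicates 2 and 3. The first principal component (36.3% of the variance) parted the controls from the 3 siRNA groups and the second (21.7%) the FOXA1 from the FOXA2 siRNA groups. The labels used here name no sequencing or library batch.

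Each siRNA group was compared with the controls within its own table, with limma 3.58.1 (R 4.3.3), an empirical Bayes trend and log2(value + 1), over genes with a mean of at least 10, and with Benjamini-Hochberg adjustment and a threshold of 0.05. All tests were two-sided. Direct comparisons between siRNA groups, the departure from additivity (double minus both singles plus control) and levels set across tables used the recovered reads of the 12 libraries, divided by median-of-ratios size factors, in 1 limma fit. Since the tables were normalized separately, levels are compared only within a table or after this joint scaling. Overlaps were set beside 20 simulations of unchanged groups against the same controls.

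Lists fixed before the data were examined covered airway regulators, secretory, ciliated and basal cell markers, squamous differentiation, tight junction, adherens junction and desmosome, ion transport, mesenchymal, migration, EGF receptor ligand, inflammatory, interferon-stimulated, cell cycle, p53 target, unfolded protein response, xenobiotic metabolism, cholesterol and fatty acid synthesis, Notch, and TGF-beta, BMP and WNT genes. Lists of fibroblast, leukocyte, endothelial, rare airway cell and alveolar, hepatic or intestinal markers stood for other cell types, and ribosomal protein and mitochondrially encoded genes for RNA quality. None of the 13 mitochondrially encoded genes was among the symbols, so that list was not tested. Lists were tested with limma's camera (preset correlation 0.01), which compares a list with the other genes tested, adjusted over all lists and the 3 comparisons against control, and in a second family for the direct comparisons, which was added after the comparisons against control had been examined. No call of a list against control held with a correlation estimated from the libraries, and 1 of the direct comparisons did.

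The genes named were chosen by a rule fixed before the data were examined: the FOXA genes and the 5 highest and 5 lowest fold changes among genes past the threshold with a mean of at least 100. It added up to 4 changed members of lists that passed or had at least 25% of their members changed and up to 2 of the others. A fixed set of genes could be given in any comparison, changed or not (CFTR, MUC5AC, MUC5B, SCGB1A1, KRT5, TP63, SPDEF, CDH1 and VIM). Sex-linked genes that could describe a donor were left out. Some genes that the rule names are not reported here.

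The labels number the libraries of each group 1 to 3. Same-numbered libraries deviated together in FOXA1 knockdown and control (correlations of 0.108, 0.112 and 0.213). They did so too in the libraries labelled FOXA2 and double knockdown (0.169, 0.160 and 0.205). These values lay above the limit of 0.1 set in advance. A fit with the replicate number as a block was made as well, and was run for all comparisons. Across all pairs of groups, correlations were -0.254 to 0.303 for the same number (median 0.110) and -0.241 to 0.205 for unlike numbers (median -0.072). Passing the limit therefore does not by itself show pairing. Alternatives planned in advance were stricter thresholds, a minimum fold, Bonferroni adjustment, no filter, other pseudocounts, TMM scaling, the block, 1 fit of all libraries, the authors' deposited table, leaving out each library, and other settings of the list test. Alternatives chosen after seeing the data were edgeR 4.0.16 (quasi-likelihood) on the recovered reads, a mean of at least 100 for counts of genes and for lists, the block and TMM scaling for lists, and for the direct comparisons and additivity all settings but the stricter threshold. Splits for additivity within replicate numbers or with the single responses removed, the direction of the departure in libraries left out, the squamous list without genes that hold a word that went with higher values, and odds ratios from logistic models, with words chosen in one FOXA2 siRNA contrast and genes called in the other, were added after seeing the data too.

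The tests were tried on simulated counts with 200 changed genes. In the FOXA1 comparison (15017 genes), limma recovered 38 of 50 genes changed by 1.5-fold, 48 of 50 by 2-fold and 50 of 50 by 3-fold, with 12 false among 198 calls. In the additivity test (14882 genes), it recovered 31 of 50 at 1.5-fold and 45 of 50 at 2-fold, with 14 false among 190 calls. False calls were 18 of 213 for FOXA2 and 17 of 208 for double knockdown against control. They were 9 of 206 for FOXA1 against FOXA2, 11 of 202 for double against FOXA1 and 11 of 204 for double against FOXA2. The false share was therefore above the adjusted p threshold in each of these simulations except FOXA1 against FOXA2. The search for siRNA seed matches regressed fold changes on the presence of each of 15957 7-base words in the longest annotated 3 prime UTR of 12907 genes, with UTR length and base composition in the model and Bonferroni adjustment (Python 3.11.15, numpy 2.4.6, scipy 1.17.1). Shuffled fold changes with nothing planted gave 0 words past the threshold. A planted word of -0.2 was ranked first with an estimate of -0.194 among 8 words past it, so 1 seed of that size can bring several words past the threshold. The words found with FOXA2 siRNA had smaller differences (-0.08 to -0.06), and recovery at that size was not tried. Figures were drawn with matplotlib 3.10.9.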

Results

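Primary human bronchial epithelial cells, the cells that line the conducting airways, were grown at an air-liquid interface and transfected with a negative control siRNA, an siRNA against FOXA1, an siRNA against FOXA2, or both together, at 30 nM per the labels, which leave the total in the double knockdown unclear. FOXA1 and FOXA2 are pioneer transcription factors of endoderm-derived epithelia. The design asks how the transcriptome changes when either factor, or both, are depleted. Polyadenylated RNA was sequenced from 3 libraries per group, 12 in all, with 22622358 to 33529530 reads assigned to genes per library and 18913 to 19253 genes with at least 1 read. The most abundant transcript was KRT6A or KRT5, with 1.75% to 2.05% of the reads of a library. Values are normalized read counts as mean ± SD (n = 3), and changes are log2 fold changes ± SE on the log2(value + 1) scale with limma's adjusted p. The labels do not say that the libraries of a group came from separate cultures or donors, so the p-values measure the spread between these libraries, which may be technical.

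The targeted genes were examined first. Normalized counts of FOXA1 mRNA in the FOXA1 knockdown were 282 ± 21.1 against 1886 ± 105 in the controls, a change of -2.74 ± 0.08 (adjusted p = 1.2e-07). It was also lower in the libraries labelled double knockdown (-2.15 ± 0.08, adjusted p = 6.2e-07) and, to a smaller extent, in the libraries labelled FOXA2 knockdown (-0.58 ± 0.06, adjusted p = 7.4e-05). FOXA2 mRNA rose in the FOXA1 knockdown by 1.58 ± 0.13 (302 ± 37.4 against 100.3 ± 13.1 in the controls, adjusted p = 2.8e-05). In the libraries labelled FOXA2 knockdown it was at 82.3 ± 24.8 against 93.7 ± 12.1 in the controls, a difference of -0.22 ± 0.20 that did not pass the test (95% interval -0.67 to 0.23, adjusted p = 0.43). In the libraries labelled double knockdown the difference from the controls did not pass either (0.09 ± 0.15, adjusted p = 0.69). Against the FOXA1 knockdown, FOXA2 mRNA fell in the double knockdown by 1.49 on the log2 scale (adjusted p = 6.2e-05). The third family member, FOXA3, had a mean of 0.286 ± 0.496 normalized counts in the controls and was below the minimum for testing in each group. Because no fall of FOXA2 mRNA below the controls passed the test in either group given FOXA2 siRNA, directions drawn from these groups are those of the libraries so labelled.

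**Figure D1:**
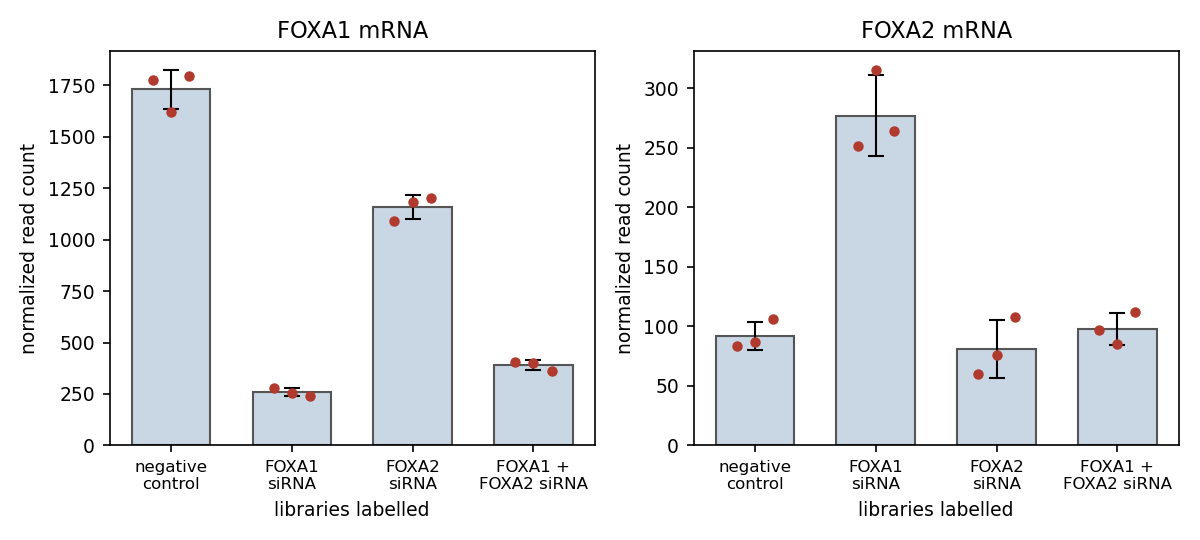
FOXA1 (left) and FOXA2 (right) mRNA as normalized read counts in the 12 libraries, normalized together. Bars are group means, error bars 1 SD and points the 3 libraries of a group. FOXA1 was lowest in both groups given FOXA1 siRNA, and FOXA2 was higher in the FOXA1 knockdown than in the other groups, with a mean of 277 ± 34.0 counts.

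The FOXA1 knockdown was then compared with the control siRNA. Members higher than in the controls were 30 of 50 squamous and cornified differentiation genes, 23 of 35 genes of cell migration and matrix remodelling, 21 of 31 of sterol and fatty acid synthesis and 13 of 26 EGF receptor ligand and MAPK feedback genes. Members lower were 22 of 49 xenobiotic metabolism genes, 15 of 44 interferon-stimulated genes and 8 of 20 ciliated cell markers. These lists passed camera with its preset correlation, and none did with an estimated correlation (adjusted p = 0.36 to 0.48). Of 15039 genes tested, 5459 changed (2817 higher, 2642 lower), 322 of them higher and 216 lower by at least 2-fold. The 5 highest among abundant genes were SPINK7, an esophageal serine protease inhibitor, which rose 11.8-fold from the control level (983 ± 106 against 83.7 ± 18.9, adjusted p = 5.5e-07), the salivary proline-rich protein genes PRB2 (2.86 ± 0.19) and PRB1 (2.61 ± 0.22), the epidermal transglutaminase TGM3 (2.81 ± 0.28) and the matricellular protein SMOC1 (2.66 ± 0.11). PRB1 and PRB2 are near-identical overlapping copies, so the split of reads between them is uncertain. The 5 lowest were FOXA1 itself, the chemokine CXCL14 (-2.46 ± 0.26), ERN2 (-2.22 ± 0.12), which overlaps PLK1 on the other strand, the club cell secretoglobin SCGB1A1 (-2.16 ± 0.27) and WNT4 (-2.15 ± 0.21).

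Of 50 squamous and cornified differentiation genes tested, 30 rose and 1 fell (34 and 1 adjusted over the list alone; camera adjusted p = 3.3e-11, and 0.36 with an estimated correlation). They included the cornified envelope genes CNFN (936 ± 53.6 against 157 ± 21.1, 5.94-fold) and SPRR3 (2.83-fold) and the ammonia transporter RHCG (0.98 ± 0.06). Migration and matrix remodelling genes rose in 23 of 35 and fell in 3 (23 and 5 adjusted over the list alone; adjusted p = 5.2e-05, and 0.48 with an estimated correlation). They included SERPINE2 (1.76 ± 0.07), the integrin subunit ITGB6 (1.05 ± 0.06) and the metalloproteinases MMP1 (1.49 ± 0.13) and MMP9 (1.59 ± 0.16). Of 34 mesenchymal genes, 15 rose and 3 fell (16 and 3 adjusted over the list alone; adjusted p = 0.0014, and 0.42 with an estimated correlation). THBS1 rose 3.25-fold and the intermediate filament gene VIM 1.87-fold, whereas E-cadherin, CDH1, was at 0.08 ± 0.06 (adjusted p = 0.33). Fibroblast markers, measured beside them as those of another cell type, had 2 higher and 1 lower of 5 tested (4 and 1 adjusted over the list alone; adjusted p = 0.38). Adherens junction and desmosome genes rose in 13 of 24 with 0 lower (13 and 1 adjusted over the list alone; adjusted p = 0.0012, and 0.48 with an estimated correlation), including PERP (0.83 ± 0.07) and the afadin gene MLLT4 (0.71 ± 0.06).

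EGF receptor ligands and MAPK feedback genes rose in 13 of 26 with 0 lower (14 and 0 adjusted over the list alone; adjusted p = 1.8e-04, and 0.48 with an estimated correlation). The ligands TGFA and AREG rose 2.18-fold and 2.15-fold. Of 31 cholesterol and fatty acid synthesis genes, 21 rose and 3 fell (the same counts adjusted over the list alone; adjusted p = 1.2e-04, and 0.36 with an estimated correlation). Among them were INSIG1 (0.88 ± 0.08) and HMGCS1, which makes the precursor of mevalonate (0.60 ± 0.05). Unfolded protein and integrated stress response genes rose in 13 and fell in 3 of 28 (13 and 4 adjusted over the list alone; adjusted p = 0.015, and 0.48 with an estimated correlation). The members with the smallest p were the cystine transporter SLC7A11 (0.68 ± 0.07), TRIB3 (0.65 ± 0.09) and CRELD2 (0.43 ± 0.07), which rose, and PHGDH (-0.53 ± 0.09), which fell.

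Of 49 xenobiotic, retinoid and antioxidant metabolism genes, 22 fell and 7 rose (25 and 8 adjusted over the list alone; adjusted p = 0.0014, and 0.36 with an estimated correlation). The aldehyde dehydrogenase ALDH3A1 was 4.32-fold lower (2739.8 ± 423 against 11822 ± 1870.0) and CYP4F11 was at -1.21 ± 0.07, while heme oxygenase HMOX1 rose 5.58-fold and the retinoic acid hydroxylase CYP26B1 2.58-fold. Interferon-stimulated genes fell in 15 and rose in 5 of 44 (19 and 7 adjusted over the list alone; adjusted p = 0.0089, and 0.48 with an estimated correlation), with USP18 at -1.02 ± 0.11. Ciliated cell markers fell in 8 of 20 and rose in 0 (the same counts adjusted over the list alone; adjusted p = 0.0089, and 0.48 with an estimated correlation). TP73, a regulator of multiciliated cells, was at -1.75 ± 0.23 and CCNO at -0.59 ± 0.13. That call was lost among genes with a mean of at least 100 (adjusted p = 0.062). Ribosomal protein genes, taken as a sign of RNA quality, fell in 25 and rose in 1 of 80 (20 and 1 adjusted over the list alone; adjusted p = 1.9e-06, and 0.77 with an estimated correlation), with a median log2 change of -0.14.

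Secretory and goblet cell markers moved both ways, 10 higher and 8 lower of 31 (the same counts adjusted over the list alone; adjusted p = 0.86). The goblet cell protein disulfide isomerase AGR2 (-1.21 ± 0.06) and MSMB (-1.80 ± 0.16) fell, and the membrane mucin MUC16 (2.33-fold) and CEACAM7 (1.98 ± 0.20) rose. SPDEF, a transcription factor of goblet cells, was 3.83-fold lower (84.9 ± 22.0 against 322 ± 27.6). The secreted mucin MUC5AC was below the minimum for testing (5.37 ± 4.89 against 8.25 ± 4.63). MUC5B was at 0.45 ± 0.44 (adjusted p = 0.46, and 0.029 without FOXA1 knockdown replicate 3, where it was at 1.01). The chloride channel CFTR, at 28.6 ± 7.07 against 20.1 ± 2.09 counts, did not pass (adjusted p = 0.18). Basal cell markers also moved both ways, 13 higher and 8 lower of 31 (the same counts adjusted over the list alone; adjusted p = 0.26). ITGA2 rose 2.59-fold, KRT15 (-1.27 ± 0.10), the neurotrophin receptor NGFR (-1.31 ± 0.09) and BCAM (-0.98 ± 0.09) fell, and KRT5 was at -0.17 ± 0.10 (adjusted p = 0.21). TP63 fell slightly (-0.30 ± 0.09, adjusted p = 0.02), a call lost without control replicate 2 (-0.30, 0.060), control replicate 3 (-0.25, 0.066), FOXA1 knockdown replicate 1 (-0.23, 0.063) or FOXA1 knockdown replicate 2 (-0.29, 0.072).

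No other list passed in the FOXA1 knockdown. Of the regulators of airway epithelium, 10 rose and 13 fell of 43 (10 and 14 adjusted over the list alone; adjusted p = 0.62), with the median at 0.01 and the mean at -0.11. ID2 (-1.61 ± 0.15) and the splicing factor RBM47 (-0.70 ± 0.06) fell and ETS1 (0.80 ± 0.07) rose. Notch signalling genes had 2 higher and 4 lower of 19 (the same counts adjusted over the list alone; adjusted p = 0.58, median 0.03, mean -0.17), with the fringe glycosyltransferase LFNG 4.34-fold lower, the ligand DLL1 at -0.92 ± 0.08 and the ligand JAG1 at 0.66 ± 0.07. TGF-beta, BMP and WNT genes rose in 13 and fell in 9 of 36 (13 and 12 adjusted over the list alone; adjusted p = 0.52), with BMP7 lower (-1.73 ± 0.13) and LTBP2 higher (1.24 ± 0.09). Ion and fluid transport genes had 12 higher and 8 lower of 39 (13 and 9 adjusted over the list alone; adjusted p = 0.29), with the proton pump ATP12A at 1.21 ± 0.07. Inflammatory genes rose in 9 and fell in 5 of 45 (the same counts adjusted over the list alone; adjusted p = 0.33), with the cytokine IL36A 5.33-fold higher. Tight junction genes rose in 8 and fell in 3 of 37 (the same counts adjusted over the list alone; adjusted p = 0.48). Cell cycle genes rose in 1 and fell in 7 of 38 (the same counts adjusted over the list alone; adjusted p = 0.17). The p53 target genes rose in 2 and fell in 6 of 27 (1 and 6 adjusted over the list alone; adjusted p = 0.47), with a median of 0.02 and a mean of -0.10.

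**Figure D2:**
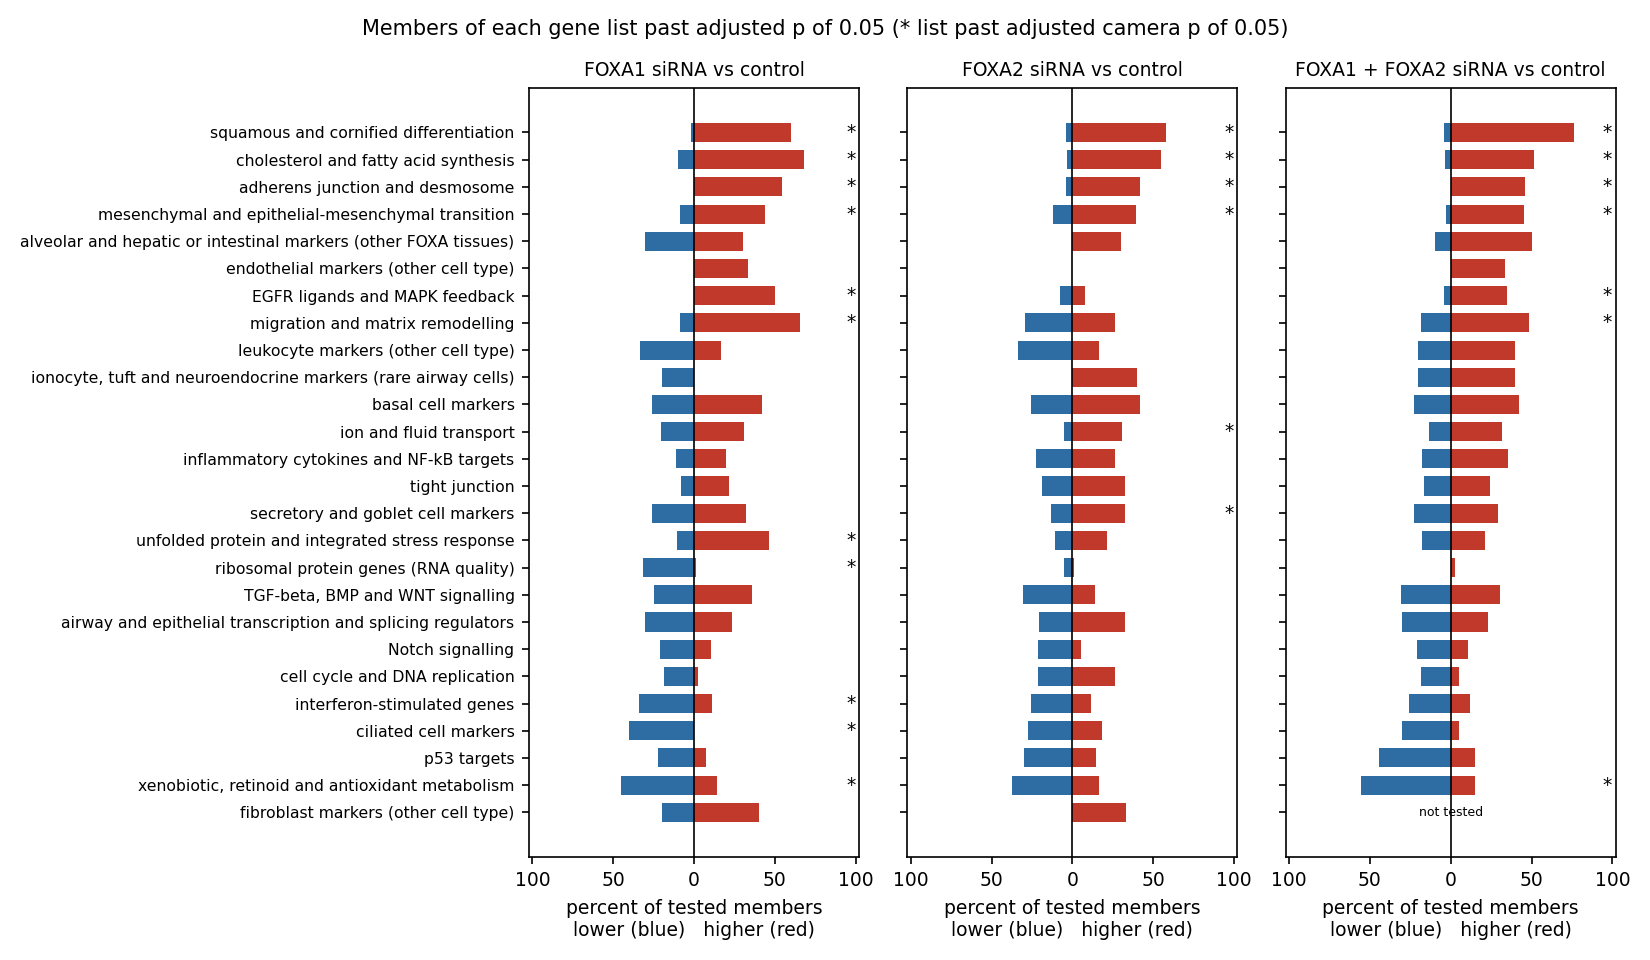
Percent of the tested members of each gene list that were higher (red, to the right) or lower (blue, to the left) at an adjusted p under 0.05 in each comparison against the control siRNA. A star marks lists past an adjusted camera p of 0.05 with the preset correlation. Squamous and cornified differentiation genes passed in each comparison, with 30, 29 and 38 of 50 members higher, but not with an estimated correlation (adjusted p = 0.36, 0.48 and 0.45).

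The libraries labelled FOXA2 knockdown, in which no fall of FOXA2 mRNA passed the test, were next compared with the control siRNA. Members higher than in the controls were 29 of 50 squamous genes, 17 of 31 sterol and fatty acid synthesis genes, 10 of 24 adherens junction and desmosome genes and 12 of 39 ion transport genes. These lists passed camera with its preset correlation, and none did with an estimated correlation (adjusted p = 0.48 to 0.55). The 5 highest among abundant genes were SPINK7 (458 ± 75.5 against 78.2 ± 17.7, 5.84-fold), CRNN, which encodes the squamous protein cornulin (2.22 ± 0.08), CD177 (2.21 ± 0.20), TGM3 (2.06 ± 0.20) and the kinase gene CDK14 (2.02 ± 0.07), which overlaps CLDN12 on the same strand. The 5 lowest were LFNG (206 ± 46.2 against 941 ± 54.7, 4.63-fold lower), ALDH3A1 (-2.09 ± 0.11), STARD3NL (-1.98 ± 0.07), the cholesterol ester hydrolase NCEH1 (-1.97 ± 0.06) and the carboxypeptidase CPA4 (-1.88 ± 0.07). The 3 prime UTRs of these 5 genes held 1 or more of the 4 7-base words that went with lower values with FOXA2 siRNA both alone and beside FOXA1 siRNA, as did those of 2 of the 5 highest genes and of 5696 of all 12907 genes searched. The words were chosen from the fold changes of these same contrasts. Of 14980 genes tested, 5562 changed (2714 higher, 2848 lower), 197 of them higher and 165 lower by at least 2-fold.

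Of 50 squamous and cornified differentiation genes, 29 rose and 2 fell in the libraries labelled FOXA2 knockdown (31 and 2 adjusted over the list alone; adjusted p = 5.7e-09, and 0.48 with an estimated correlation), among them SPRR3 (1.36 ± 0.08), RHCG (1.02 ± 0.07) and A2ML1 (0.85 ± 0.07). Cholesterol and fatty acid synthesis genes rose in 17 and fell in 1 of 31 (the same counts adjusted over the list alone; adjusted p = 1.9e-04, and 0.48 with an estimated correlation), with INSIG1 2.1-fold and MVD 1.65-fold higher. Adherens junction and desmosome genes rose in 10 and fell in 1 of 24 (10 and 3 adjusted over the list alone; adjusted p = 0.0027, and 0.55 with an estimated correlation), with DSC2 at 0.62 ± 0.07 and PERP at 0.63 ± 0.07. Of 39 ion and fluid transport genes, 12 rose and 2 fell (the same counts adjusted over the list alone; adjusted p = 0.011, and 0.48 with an estimated correlation). They included the epithelial sodium channel subunit SCNN1B (1.27 ± 0.08), the potassium channel KCNMA1 (1.41 ± 0.07) and ATP12A (1.15 ± 0.07). CFTR was at 0.00 ± 0.25 (adjusted p = 0.99). Mesenchymal genes rose in 13 and fell in 4 of 33 (the same counts adjusted over the list alone; adjusted p = 0.017, and 0.48 with an estimated correlation). VIM (1045 ± 160.4 against 285 ± 5.44, 3.62-fold) and TGFBI (1.14 ± 0.08) rose and MYL9 (-0.97 ± 0.11) fell. Fibroblast markers had 1 higher and 0 lower of 3 tested (the same counts adjusted over the list alone; adjusted p = 0.34).

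Secretory and goblet cell markers rose in 10 and fell in 4 of 31 (11 and 4 adjusted over the list alone; adjusted p = 0.031, and 0.48 with an estimated correlation), a call lost when ranks replaced values (adjusted p = 0.060). The membrane mucins MUC21 (1.35 ± 0.08), MUC16 (0.91 ± 0.11) and MUC15 (0.69 ± 0.08) rose. SPDEF fell (-0.95 ± 0.10, adjusted p = 7.4e-05), and SCGB1A1 was at -0.35 ± 0.16 (adjusted p = 0.11), which passed with the replicate number as a block (0.0050) and without FOXA2 knockdown replicate 1 (-0.50, adjusted p = 0.040). EGF receptor ligands and MAPK feedback genes rose in 2 and fell in 2 of 26, the same counts adjusted over the list alone (camera adjusted p = 0.43, and 0.021 with the replicate number as a block). ETV5, an ETS factor induced by MAPK signalling, was 2.63-fold lower. Its 3 prime UTR holds all 4 of the words that went with lower values, chosen from fold changes that include its own. Xenobiotic metabolism genes fell in 18 and rose in 8 of 48 (19 and 9 adjusted over the list alone) without passing as a list (adjusted p = 0.12). NQO1 was at -0.64 ± 0.05 and ALDH3A2 at -0.91 ± 0.05. Interferon-stimulated genes, 11 lower and 5 higher of 43 (13 and 5 adjusted over the list alone), did not pass either (adjusted p = 0.12), with USP18 at -1.25 ± 0.11. Among single genes, the basal cell collagen COL17A1 rose 2.05-fold. NGFR (-1.02 ± 0.08), the cyclin CCND1 (-0.83 ± 0.05), the cell adhesion receptor ICAM1 (-1.27 ± 0.10), the amino acid transporter SLC7A5 (-1.08 ± 0.08), SFRP1 (-1.19 ± 0.07) and TP63 (-0.37 ± 0.06, adjusted p = 0.0012) fell. KRT5 was at 0.08 ± 0.09 (adjusted p = 0.53). Ribosomal protein genes had 1 higher and 4 lower of 80 (1 and 2 adjusted over the list alone; adjusted p = 0.38). Of the lists that did not pass, the median and mean differed in sign for airway regulators (0.09 and -0.05, adjusted p = 0.51), Notch signalling (0.02 and -0.21, 0.51) and cell cycle genes (0.04 and -0.01, 0.83). Migration genes had a median of -0.08 while the test pointed upward (adjusted p = 0.83).

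In the libraries labelled double knockdown, which received both siRNAs, 38 of 50 squamous genes rose and 26 of 47 xenobiotic metabolism genes fell against the control siRNA. Both lists passed camera with its preset correlation and neither with an estimated correlation (adjusted p = 0.45 for each). The 5 highest among abundant genes were SPINK7 (861 ± 40.8 against 77.4 ± 17.4, 11.2-fold), the late cornified envelope gene LCE3D (3.29 ± 0.18), IGFN1 (3.28 ± 0.16), PRB2 (3.17 ± 0.18) and PRB1 (2.87 ± 0.18). The 5 lowest were ALDH3A1 (987 ± 159 against 10936 ± 1738, 11.1-fold lower), LFNG (-2.63 ± 0.18), WNT10A (-2.42 ± 0.20), WNT4 (-2.40 ± 0.15) and SDPR (-2.39 ± 0.14), which encodes a caveolar protein. Of 14939 genes tested, 5098 changed (2504 higher, 2594 lower), 366 of them higher and 311 lower by at least 2-fold.

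Of 50 squamous and cornified differentiation genes, 38 rose and 2 fell in the libraries labelled double knockdown (40 and 2 adjusted over the list alone; adjusted p = 3.0e-16, and 0.45 with an estimated correlation), with CNFN 6.07-fold higher, CRCT1 at 2.32 ± 0.12 and involucrin, IVL, 2.64-fold higher. Xenobiotic, retinoid and antioxidant metabolism genes fell in 26 and rose in 7 of 47 (28 and 9 adjusted over the list alone; adjusted p = 1.3e-04, and 0.45 with an estimated correlation). The glutathione peroxidase GPX2 (-1.48 ± 0.08) and ALDH3A2 (-1.40 ± 0.06) fell, and the vitamin D hydroxylase CYP24A1 (1.45 ± 0.07) rose. Mesenchymal genes rose in 15 and fell in 1 of 33 (16 and 2 adjusted over the list alone; adjusted p = 2.0e-04, and 0.36 with an estimated correlation), with VIM 4.85-fold higher (1391 ± 261 against 283 ± 5.14). Migration genes rose in 16 and fell in 6 of 33 (17 and 8 adjusted over the list alone; adjusted p = 0.0089, and 0.48 with an estimated correlation), with MMP9 5.59-fold and ANGPTL4 3.59-fold higher. Cholesterol and fatty acid synthesis genes rose in 16 and fell in 1 of 31 (17 and 2 adjusted over the list alone; adjusted p = 6.6e-04, and 0.36 with an estimated correlation), including INSIG1 (1.31 ± 0.10) and MVD (1.05 ± 0.07). Adherens junction genes rose in 11 and fell in 0 of 24 (the same counts adjusted over the list alone; adjusted p = 0.0011, and 0.48 with an estimated correlation). EGF receptor ligands and MAPK feedback genes rose in 9 and fell in 1 of 26 (the same counts adjusted over the list alone; adjusted p = 0.0088, and 0.6 with an estimated correlation). DSC2 was at 0.73 ± 0.06, EPGN at 0.76 ± 0.11 and ETV5 at -0.94 ± 0.09.

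Secretory and goblet cell markers went both ways in the libraries labelled double knockdown, 9 higher and 7 lower of 31 (the same counts adjusted over the list alone; adjusted p = 0.58). AGR2 was 4.27-fold, SPDEF 4.41-fold and SCGB1A1 3.19-fold lower, while MUC21 rose 2.93-fold and MUC4 1.76-fold. MUC5AC was below the minimum (3.46 ± 1.69 against 7.63 ± 4.28), and MUC5B (0.54 ± 0.35, adjusted p = 0.28) and CFTR (0.47 ± 0.24, adjusted p = 0.16) did not pass. Ciliated cell markers fell in 6 and rose in 1 of 20 (6 and 2 adjusted over the list alone; adjusted p = 0.094), and p53 target genes fell in 12 and rose in 4 of 27 (13 and 4 adjusted over the list alone; adjusted p = 0.1). Neither list passed. ID2 (-2.05 ± 0.10), KRT15 (2.33-fold lower) and TP63 (-0.54 ± 0.07, adjusted p = 3.3e-04) fell, and SOX9 (1.46 ± 0.14), COL17A1 (1.02 ± 0.11) and IL36A (2.63 ± 0.19) rose. KRT5 (0.01 ± 0.13, adjusted p = 0.97) and CDH1 (0.05 ± 0.07, adjusted p = 0.62) did not pass. The median and mean differed in sign for ion transport (-0.03 and 0.20, adjusted p = 0.38), airway regulators (0.01 and -0.15, 0.69), Notch signalling (0.03 and -0.19, 0.79) and the rare cell markers (-0.07 and 0.23, 0.69), and fibroblast markers were too few to be tested.

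**Figure D3:**
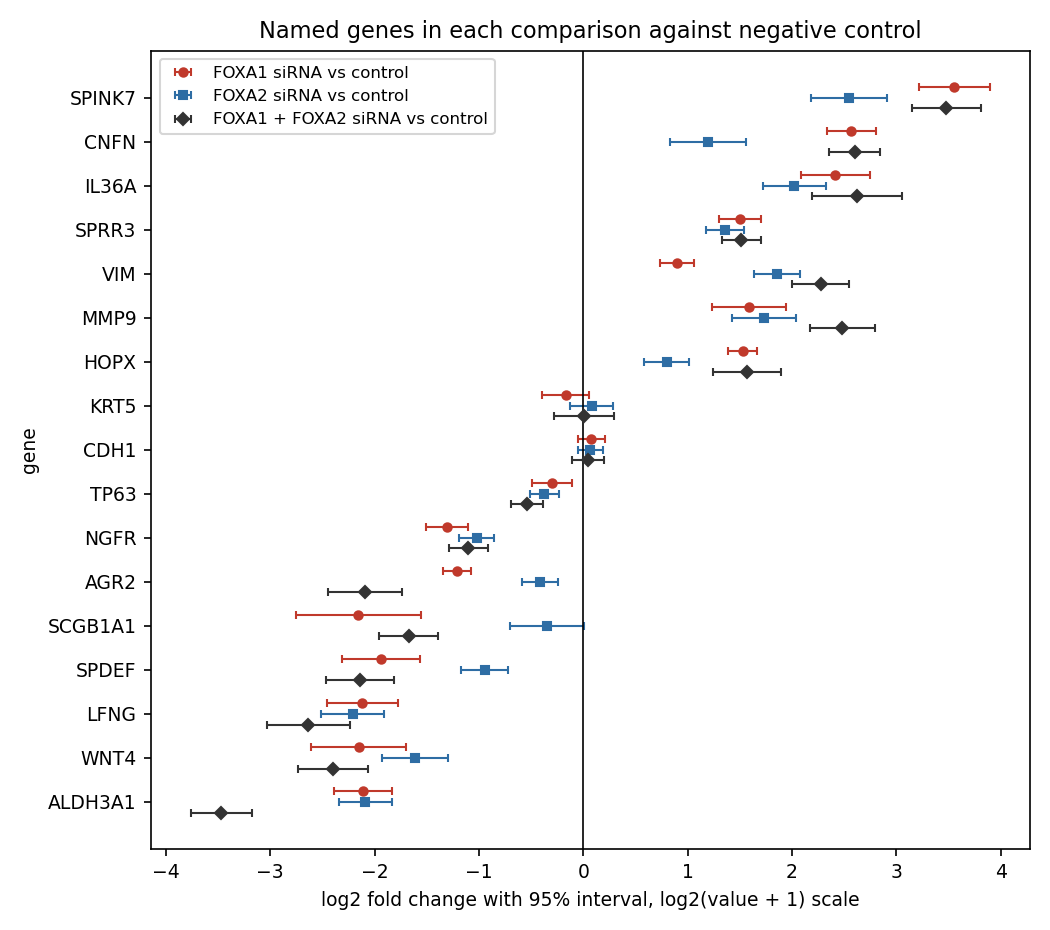
Log2 fold change against the control siRNA, on the log2(value + 1) scale, with the 95% interval, for 17 of the named genes in the FOXA1 knockdown (red circles), the libraries labelled FOXA2 knockdown (blue squares) and those labelled double knockdown (dark diamonds), 3 libraries a group. SPINK7 was higher in each comparison and ALDH3A1 lower, with the double knockdown at -3.47, while the intervals of KRT5 and CDH1 include 0.

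The 3 comparisons share the control libraries, so their chance values are shared too. FOXA1 and FOXA2 comparisons had 1385 genes higher and 1250 lower in both, with 283 in opposite directions, where independent lists would give 506.0, 505.0 and 1012.5. Pearson's r across 14882 genes was 0.585, against 0.498 for simulated unchanged groups, and the covariance was 0.0949 against 0.0133. FOXA1 and double knockdown had 1566 genes higher and 1423 lower in both and 104 opposite (468.6, 459.7 and 929.5 for independent lists), with r of 0.761 (simulated 0.497) and a covariance of 0.151 (simulated 0.0134). FOXA2 and double knockdown had 1664 higher and 1835 lower in both and 26 opposite (450.6, 497.3 and 946.8), with r of 0.800 (simulated 0.491) and a covariance of 0.143 (simulated 0.0132). In all 3 comparisons 1136 genes were higher and 1048 lower. The 20 simulations gave 0 such genes and, for the pairs, 0.05, 0.1 and 0 genes called alike on average; as unchanged groups hold no effects to call, these counts do not measure what shared controls add among called genes. Genes are not independent replicates, and since 3 controls cannot be split into parts of 2, part of the excess may come from the shared controls.

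The knockdowns were compared directly with each other in 1 fit of the 12 libraries. Between the FOXA1 knockdown and the libraries labelled FOXA2 knockdown, 4666 of 14944 genes differed, 2490 higher and 2176 lower with FOXA1 siRNA. AKAP12, a scaffold for protein kinase A (2.52 ± 0.22), the neuronal navigator NAV3 (2.37 ± 0.14), HMOX1 (2.21 ± 0.20), ETV5 (2.09 ± 0.08) and the cell adhesion gene NRCAM (1.95 ± 0.08) were the highest. CXCL14 (-2.37 ± 0.24), ERN2 (-2.32 ± 0.13), FOXA1 (-2.16 ± 0.08), SCGB1A1 (-1.81 ± 0.25) and TREM1 (-1.79 ± 0.29) were the lowest. SPDEF was 1.99-fold lower with FOXA1 siRNA (adjusted p = 4.5e-04), as was VIM (-0.96 ± 0.12, adjusted p = 4.1e-05). KRT5 was at -0.25 ± 0.10 (adjusted p = 0.073), and passed with edgeR on the recovered reads (0.013) and with only the 2 groups in the fit (0.046). Among the lists, migration genes had 17 higher and 1 lower of 34 (the same counts adjusted over the list alone; adjusted p = 1.2e-05, and 0.26 with an estimated correlation). EGF receptor ligands had 9 higher and 2 lower of 26 (the same counts adjusted over the list alone; adjusted p = 0.021, and 0.76 with an estimated correlation). Xenobiotic metabolism (16 lower, 5 higher of 48; 17 and 5 adjusted over the list alone), ciliated (6 lower, 0 higher of 21; the same counts adjusted over the list alone) and ribosomal protein genes (9 lower, 1 higher of 80; 4 and 0 adjusted over the list alone) were lower with FOXA1 siRNA as lists. Their adjusted p was 0.019, 0.019 and 0.0018, and 0.26, 0.46 and 0.91 with an estimated correlation. The secretory list (adjusted p = 0.026; 9 lower and 2 higher of 31) and the TGF-beta, BMP and WNT list (0.048; 14 higher and 6 lower of 36) were past the threshold too. Both lost it when ranks replaced values (0.057 and 0.055) and with an estimated correlation (0.69 and 0.55). The second also lost it with TMM scaling (0.051) and among genes with a mean of at least 100 (0.10). The squamous list did not pass between these groups (adjusted p = 0.058). Nor did the ion transport, p53 target, fibroblast and adherens junction lists, whose median, mean and test differed in sign.

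The libraries labelled double knockdown, with FOXA2 siRNA added to FOXA1 siRNA, differed from the FOXA1 knockdown in 3560 genes (1629 higher, 1931 lower). VIM (1.38 ± 0.12), IGFN1 (1.88 ± 0.20), TREM1 (1.68 ± 0.29) and the squamous genes CDSN (1.46 ± 0.20) and LCE3D (1.34 ± 0.23) were the highest, and the peroxisomal import factor PEX19 (-1.88 ± 0.08), CPA4 (-1.64 ± 0.07), ETV5 (-1.63 ± 0.08), ARL6IP1 (-1.57 ± 0.06) and STARD3NL (-1.53 ± 0.08) the lowest. The 3 prime UTRs of these 5 lowest genes, and of 1 of the 5 highest, held 1 or more of the 4 words that went with lower values with FOXA2 siRNA. So did those of 5696 of all 12907 genes searched. The words were chosen in part from the fold changes of this same contrast, so these counts are no separate support for them. FOXA1 mRNA was higher in the double knockdown than in the FOXA1 knockdown (0.59 ± 0.08, adjusted p = 9.9e-05). A weaker FOXA1 knockdown is therefore not told apart from the added FOXA2 siRNA as a source of these differences. SPDEF (-0.20 ± 0.17, adjusted p = 0.42) and SCGB1A1 (0.48 ± 0.25, adjusted p = 0.17) did not pass. The squamous list was higher (18 higher and 3 lower of 50; 21 and 3 adjusted over the list alone; adjusted p = 7.6e-04, and 0.76 with an estimated correlation). Ribosomal protein genes were higher too (17 and 0 of 80; 13 and 0 adjusted over the list alone; adjusted p = 4.3e-08, and 0.76 with an estimated correlation), as were leukocyte markers (4 and 0 of 5, the same counts adjusted over the list alone; adjusted p = 0.0023, and 0.44 with an estimated correlation). The median, mean and test differed in sign for cholesterol and ion transport genes, which did not pass.

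The libraries labelled double knockdown differed from those labelled FOXA2 knockdown in 1219 genes (647 higher, 572 lower). That count fell to 455 without FOXA2 knockdown replicate 1, 667 without FOXA2 knockdown replicate 2, 525 without double knockdown replicate 2 and 592 without double knockdown replicate 3, and rose to 2217 without double knockdown replicate 1. PRB2 (1.98 ± 0.22), PRB1 (1.86 ± 0.25), LCE3D (1.54 ± 0.23), NAV3 (1.53 ± 0.14) and the plasminogen activator PLAT (1.51 ± 0.26) were the highest, and ERN2 (72.5 ± 11.7 against 292 ± 37.0 counts), CXCL14 (-1.73 ± 0.24), AGR2 (-1.68 ± 0.14), FER1L6 (-1.60 ± 0.15) and FOXA1 (-1.57 ± 0.08) the lowest. SCGB1A1 (-1.33 ± 0.25, adjusted p = 0.0047) and SPDEF (-1.20 ± 0.17, adjusted p = 9.1e-04) fell. The squamous list was higher, 24 members up and 0 down of 50 (28 and 3 adjusted over the list alone; adjusted p = 4.9e-13, and 0.35 with an estimated correlation). Xenobiotic metabolism genes were lower, 19 down and 6 up of 48 (27 and 7 adjusted over the list alone; adjusted p = 7.1e-07), the 1 list call that held with an estimated correlation (adjusted p = 0.028). Migration (12 higher, 1 lower of 34; 13 and 1 adjusted over the list alone), inflammatory (9 higher, 1 lower of 45; 13 and 3 adjusted over the list alone), mesenchymal (8 higher, 0 lower of 33; 11 and 1 adjusted over the list alone) and EGF receptor ligand genes (6 higher, 0 lower of 26; 7 and 0 adjusted over the list alone) were higher as lists. Their adjusted p was 1.1e-05, 2.9e-05, 9.2e-04 and 0.0036, and 0.26, 0.76, 0.26 and 0.76 with an estimated correlation. Ciliated markers were lower (4 lower and 0 higher of 21, 7 and 0 adjusted over the list alone; adjusted p = 0.0061, and 0.37 with an estimated correlation). Ribosomal protein genes passed as a list toward higher values (adjusted p = 0.027, and 0.91 with an estimated correlation) with a median of 0.05, although 0 of 80 passed singly. Ion transport genes, 9 lower and 2 higher of 39 (adjusted p = 0.18), passed among genes with a mean of at least 100 (0.042). The median, mean and test differed in sign for the tight junction and Notch lists, which did not pass.

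The combined response was last compared with the sum of the single responses. Of 14944 genes, 2159 departed from the sum, 958 upward and 1201 downward. For genes that both single siRNAs changed in the same direction in 2 libraries per group, the departure was measured in the libraries of the number left out, which took no part in choosing them. With replicates 1, 2 and 3 left out in turn, 1700 of 1788, 1098 of 1138 and 2021 of 2276 such genes changed less in the double knockdown than the sum, where additive responses would give 50%. Genes are not independent, and these shares have no test. A change shared by all siRNA groups against the controls would also give shares above 50%, without any interaction of FOXA1 and FOXA2. FOXA1 mRNA was also 0.59 higher on the log2 scale in the double than in the FOXA1 knockdown. The double knockdown therefore did not combine the 2 single knockdowns at equal depletion. SPINK7, 11.8-fold higher with FOXA1 siRNA, 5.84-fold in the libraries labelled FOXA2 knockdown and 11.2-fold with both, fell short of the sum by -2.62 ± 0.20 (adjusted p = 4.0e-06), and the cadherin CDH6 by -2.84 ± 0.12 (adjusted p = 4.5e-09). The count was 1401 without control replicate 1, 1287 without FOXA2 knockdown replicate 1, 1367 without FOXA2 knockdown replicate 3 and 1310 without double knockdown replicate 2.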

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

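The 3 tests of the FOXA2 transcript, the squamous list without genes holding a word, the odds ratios and the splits for additivity with the single responses removed were chosen after the results were seen. The other tests below were chosen before their own results but after the changes against control had been examined.

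The change that went with FOXA2 siRNA differed for 2159 genes between libraries without and with FOXA1 siRNA. This was the test of the difference itself in 1 limma fit of the 12 libraries. For the genes named by the rule, 3 log2 values are given in order. They are FOXA2 knockdown against control, double against FOXA1 knockdown, and their difference. In the second contrast FOXA1 mRNA was 0.59 higher, and the labels leave the siRNA total of the double knockdown unclear. A weaker FOXA1 knockdown is therefore not told apart there from the added FOXA2 siRNA. CDH6 was at 1.32 and -1.52, a difference of -2.84. SPINK7 was at 2.55 and -0.07, a difference of -2.62, and TGM3 at 2.06 and -0.25, a difference of -2.31. CDK14 was at 2.03 and -0.16, a difference of -2.19, and CALB1 at 0.96 and -1.06, a difference of -2.02. FOXA2 itself was at -0.22 and -1.49, a difference of -1.28, and FOXA1 at -0.58 and 0.59, a difference of 1.17. SMIM3 was at -0.88 and 0.38, a difference of 1.25, DLL1 at -1.02 and 0.26, a difference of 1.28, and IL32 at -1.02 and 0.27, a difference of 1.29. WNT4 was at -1.61 and -0.24, a difference of 1.36, and LFNG at -2.21 and -0.52, a difference of 1.69. SPDEF was at -0.94 and -0.20, a difference of 0.74 with an adjusted p of 0.0497. The SPDEF call held without FOXA1 knockdown replicate 2 or without double knockdown replicate 1, and without each of the other 10 libraries the adjusted p was 0.0542 to 0.114. It was also lost without the filter on low values, with a pseudocount of 0.5 and with Bonferroni adjustment. The single responses were removed with an additive fit, and its residuals were exchanged among the libraries in 100 splits. The real split alone, 1 of 100, gave as many genes as 2159, a share under 0.05. The highest other split gave 72 with exchange among all libraries and 1866 within replicate numbers. These splits treat the libraries as independent, and their spread may be technical, so chance differences between cultures or transfections are not excluded. Exchanging the groups themselves gave 3 of 100 (highest other 3392), which decides nothing because the single responses then enter the spread. By arithmetic, a change shared by all siRNA groups against the controls enters the sum of the single responses once for each and the combined response a single time.

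For the comparisons of 3 libraries with 3, 1 of the 10 splits, the real one, gave as many genes, and 10 splits are too few for a share under 0.05. The real counts were 5459 (FOXA1 against control), 5562 (FOXA2), 5098 (double), 4666 (FOXA1 against FOXA2), 3560 (double against FOXA1) and 1219 (double against FOXA2). The highest other split gave 19 genes for double against FOXA1 and 0 for each of the rest. Each other split mixes libraries of both groups, so differences between the groups enter its spread. How low these other counts are therefore decides nothing.

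The squamous list was higher in each comparison against control, and these comparisons share the control libraries. The controls as the whole cause are argued against by the double knockdown against the libraries labelled FOXA2 knockdown, which holds no control: 24 of 50 members were higher and 0 lower (camera p = 6.2e-15; adjusted p = 0.35 with an estimated correlation). Of 15957 7-base words searched in 3 prime UTRs, 0 passed as going with higher fold changes in all 3 comparisons, but this does not exclude seed effects of the control siRNA: 6 words that share GGAGA passed in 1 comparison each, and their 95% intervals lay above 0 in all 3. Direct matches to these words as the whole cause are argued against, since without the genes that hold one the squamous list stayed past the threshold (highest adjusted p 3.0e-08, preset correlation), and of 23 squamous genes higher in all 3 comparisons no 7-base word was held by more than 10. Seed effects of the control siRNA as a part, loss of FOXA1 or FOXA2, off-target effects of their siRNAs and the total amount of siRNA in the double knockdown, which the labels leave unclear, stay open.

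Of the genes tested, 963 were lower with FOXA2 siRNA both alone and beside FOXA1 siRNA, in contrasts that share no library. Off-target binding through the siRNA seed may account for part of them: 4 words that overlap in pairs (TGCTGTA, CTCCTCT, TTGCTGT and TCCTCTA) went with lower fold changes in both contrasts (highest Bonferroni p 2.2e-13, 5.0e-12, 2.3e-09 and 3.5e-05). Averaged over all genes that hold it, each of the 4 words went with a difference of -0.08 to -0.06 on the log2 scale. Words past the threshold were not particular to lower values. With FOXA2 siRNA alone 5 went with lower and 5 with higher values, and beside FOXA1 siRNA 9 and 10. The words that went with higher values were not the same in these contrasts, and their cause was not tested. For FOXA1 siRNA, 1 word (TGTTTCA) went with lower values against control (-0.05, Bonferroni p 4.4e-04) and 0 did so in both of its contrasts. Its second contrast, double against FOXA2 knockdown, had 0 words past the threshold in either direction. TGTTTCA was also lower in the FOXA1 against the FOXA2 knockdown (-0.05, Bonferroni p 4.4e-04) and higher in double against FOXA1 knockdown (0.04, Bonferroni p 5.5e-06). Seed effects of the FOXA1 siRNA therefore stay open. Of the 1832 genes lower beside FOXA1 siRNA, 68.8% held a word chosen in the other contrast, against 42.5% of the rest (odds ratio 2.27, 95% interval 2.01 to 2.57, adjusted for UTR length and composition), and the reverse gave 1.61 (1.44 to 1.80). UTR length and composition predicted at most 6.84% of the mean change. These genes were chosen for being low, so any weak predictor would give a small share, and this does not exclude the 2 properties. The association with the words held with both properties in the model. A match of the words to a seed was not tested, as the siRNA sequences were not used here, and loss of FOXA2 protein stays open.

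No fall of FOXA2 mRNA against the controls passed the test in the libraries labelled FOXA2 knockdown. In the double knockdown against the FOXA1 knockdown this transcript was lower, at a log2 change of -1.49. FOXA1 mRNA was 0.59 higher on the log2 scale in that contrast. A smaller rise of FOXA2 with a weaker FOXA1 knockdown is therefore not told apart from an effect of the FOXA2 siRNA. An siRNA without effect on this transcript stays open. Too few reads are argued against by the lower end of the 95% interval against control, -0.67, which lies above a halving on the log2 scale. The estimate was -0.44 without FOXA2 knockdown replicate 3 and -0.02 without replicate 1. Without replicate 3 the 95% interval lay below 0 (-0.83 to -0.05, limma adjusted p = 0.080), so a moderate fall is not excluded. With each library left out in turn the lower end was -0.83 to -0.45. Labels exchanged with the double knockdown are argued against by FOXA1, which was at -1.57 in the libraries labelled double knockdown against those labelled FOXA2 knockdown. Candidate explanations that stay open are a rise of FOXA2 transcription that offsets its knockdown and a wrong label of another kind. In the reference used here FOXA2 overlaps AL121722.1 on the same strand, so reads of that gene counted as FOXA2 stay open too. None of these was tested, and protein was not analysed here.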

How the results depend on the processing

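Tests and settings chosen after seeing the data were edgeR, the mean of at least 100 for counts of genes and lists, the block and TMM scaling for lists, and for direct comparisons and additivity all but the stricter threshold. Counts below are in the order FOXA1, FOXA2 and double knockdown against control, FOXA1 against FOXA2, double against FOXA1, double against FOXA2, and additivity. An adjusted p under 0.01 gave 3228, 3317, 3079, 2873, 1891, 450 and 728 genes. A log2 change of at least 1 gave 538, 362, 677, 331, 148, 134 and 227, and Bonferroni adjustment 430, 515, 476, 572, 344, 61 and 122, each fewer by construction. Leaving out 1 library gave 4060 to 5356, 4213 to 5239, 3587 to 5579, 3618 to 4527, 2569 to 3717, 455 to 2217 and 1287 to 3098 genes, with 2 libraries left in 1 group. The count for double against FOXA2 was 455 without FOXA2 knockdown replicate 1, 667 without FOXA2 knockdown replicate 2, and 2217, 525 and 592 without double knockdown replicates 1, 2 and 3. That for additivity was 1401 without control replicate 1, 1287 and 1367 without FOXA2 knockdown replicates 1 and 3, and 1310 without double knockdown replicate 2. FOXA1 ranged from -2.79 to -2.69, -0.63 to -0.54 and -2.20 to -2.10 against control, and FOXA2 from 1.48 to 1.69, -0.44 to -0.02 and -0.01 to 0.19. The calls of both targets against control were kept under each alternative run, and the additivity call of FOXA2 was lost with Bonferroni adjustment alone. With the replicate number as a block the counts were 5773, 6130, 4023, 4534, 3319, 1094 and 1852. Of the named genes and lists, SCGB1A1 and the EGF receptor ligand list with FOXA2 siRNA passed with the block (adjusted p 0.0050 and 0.021), and it changed no other call of these. The pairing limit was not met for the other pairs of groups, and 8 of 12 libraries correlated best with their own number. edgeR gave 5506, 5582, 5184, 4727, 3566, 1205 and 2181, and the authors' deposited table called 4932, 4947 and 4779 for the comparisons against control. Of these, 4815, 4857 and 4620 were called here in the same direction. Genes changed alike in pairs of comparisons numbered 1365, 1656 and 1989 at an adjusted p under 0.01, and Pearson's r across genes with a mean of at least 100 was 0.573, 0.752 and 0.835. A preset correlation of 0.05 left 6 of 11, 2 of 6, 1 of 7 and 4 of 8 lists for FOXA1, FOXA2, FOXA1 against FOXA2 and double against FOXA2. An estimated correlation left 0 lists in each comparison except double against FOXA2, where it left 1. Of 384 results for single named genes, 347 were called, 332 of these kept their call under each alternative but Bonferroni, 15 lost it under 1 or more, 4 others passed under 1 or more, and 0 reversed. A mean of at least 10 coincides with the filter used, the shared-control standard errors did not apply, and centring changes nothing in camera. Apart from the Bonferroni and fold limits, the cause of these shifts was not tested. Depth limits genes with few reads, such as FOXA3 and MUC5AC.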

Other observations

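Markers of other tissues and cell types were measured as lists fixed before the data were examined, and no list here passed against control. HOPX, a homeodomain protein of alveolar and squamous epithelium, rose 2.89-fold in the FOXA1 knockdown (10616 ± 456 against 3680.3 ± 237, adjusted p = 4.8e-07), 1.74-fold in the libraries labelled FOXA2 knockdown and 2.96-fold in those labelled double knockdown. The surfactant gene SFTPA1 rose from few counts (43.0 ± 6.1 against 8.15 ± 1.83 in the double knockdown, adjusted p = 1.7e-04), although its reads cannot be told from those of SFTPA2. Of the alveolar, hepatic and intestinal markers, 3 rose and 3 fell of 10 with FOXA1 siRNA (adjusted p = 0.52). The counts were 3 and 0 in the libraries labelled FOXA2 knockdown (0.36) and 5 and 1 in those labelled double knockdown (0.18).

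CD68, a lysosomal glycoprotein also used as a macrophage marker, rose 1.99-fold in the libraries labelled FOXA2 knockdown (adjusted p = 8.0e-07), whereas CD14 fell (-0.71 ± 0.14, adjusted p = 0.0024). The leukocyte list had 1 higher and 2 lower of 6 with FOXA1 siRNA (adjusted p = 0.38). It had 1 higher and 2 lower in the libraries labelled FOXA2 knockdown (0.83) and 2 and 1 of 5 in those labelled double knockdown (0.47). The endothelial list had 1, 0 and 1 higher of 3 (adjusted p = 0.22, 0.95 and 0.42). The member that rose was ERG, an ETS factor, at 1.14 ± 0.21 with FOXA1 siRNA and 1.17 ± 0.22 with both. The markers of ionocytes, tuft and neuroendocrine cells had 0, 2 and 2 higher and 1, 0 and 1 lower of 5 (adjusted p = 0.79, 0.62 and 0.69). The tuft cell factor ASCL2 was at -1.04 ± 0.24 with FOXA1 siRNA and -1.02 ± 0.25 with both. ETV5 was among the 283 genes that went in opposite directions with the single siRNAs. It was at 0.70 ± 0.08 with FOXA1 siRNA and -1.39 ± 0.09 in the libraries labelled FOXA2 knockdown. Its 3 prime UTR holds all 4 of the 7-base words that went with lower values with FOXA2 siRNA. These words were chosen from fold changes that include those of ETV5.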
